A study of Mus musculus with 19 samples.

How the data were processed

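Cortical RNA from 19 libraries of male P301S/E4 mice was compared between 10 lemborexant and 9 vehicle libraries. Per the labels' protocols, frozen cortex was homogenised with TRIzol and chloroform, RNA was purified on Qiagen columns, and libraries were made with a Takara SMARTer Ultra Low kit. The series' design text speaks of triplicates, while the labels give 10 and 9 libraries, and the labels were followed. Groups were taken from the titles and treatment labels, and replicates were numbered within each group, since the labels give library numbers (859 to 933 and 1064 to 1602) but no replicate number. Per the submitters' processing notes, reads were processed with bcl2fastq and DRAGEN 3.9.3-8 on GRCm38. The annotation release, the strand setting and any filters are not given in the sources used here, so a gene cannot be told from an antisense gene that overlaps it.

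The deposited tables hold, per the file headers, an estimated count (NumReads), a TPM value and an effective length for each of 55487 genes. The estimated counts need not be whole, because reads shared between genes were divided by the authors' program, and they were rounded to whole numbers for every count test. The deposited TPM values are relative to the total of each library and to gene length, and they were used for 2 alternatives. Gene symbols, biotypes and coordinates came from GENCODE's GRCm38 annotation, which held a symbol for 55141 of the identifiers.

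The main test was edgeR 4.0.16's quasi-likelihood test with robust dispersion, TMM factors and edgeR's expression filter on all 19 libraries (R 4.3.3). It was two-sided, with Benjamini-Hochberg adjustment over 19105 genes and a threshold of 0.05. Levels are CPM with TMM factors, log2 CPM used a prior count of 2, and the SE of a log2 change was taken as its size divided by the square root of the F statistic. The biological coefficient of variation was 0.319. A set of 37 gene lists was tested with limma 3.58.1's camera at a preset correlation of 0.01, adjusted over the 36 lists with at least 5 tested members, and beside it with an estimated correlation and with fry. The list of the orexin peptide and its receptors was too short to test. A list score is the mean over its genes of log2 CPM centred on the mean of all libraries. The lists, the edgeR, camera and fry tests above and the rule for named genes were fixed before the data were examined.

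Genes named are the 8 with the largest log2 change in each direction among those past the threshold with a mean of at least 1 CPM. A panel of 17 genes is always given. For each list past the threshold the 3 members with the smallest p in its direction are named, and for other lists described in words 2. The results of 4 genes chosen by these rules are not reported, and these genes were left out of the search for outlying libraries. Gene models without a gene name are counted and not named, and 49 of the 498 called genes were of that kind. Single values between groups were tested with exact permutation over all 92378 splits of the libraries, and over all 11440 splits of 16 units with the values of each nearly alike pair averaged, which was added after seeing the data.

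Every pair of libraries was compared by a chi-square of counts over genes with at least 20 reads in the pair, and fits were repeated with the 3 nearly alike pairs summed. The tests were checked on counts simulated from the means, dispersions and library sizes of the 10 and 9 libraries with 18841 genes tested. Of 100 genes changed 1.5-fold, 36% were recovered, and of 100 changed 2-fold, 65% were, with 6 false calls among 124. The 124 also include genes of the oxidative phosphorylation list, which was raised 1.5-fold in the simulation. The simulation drew the nearly alike pairs as independent libraries, so these shares do not hold if the pairs are repeats of 1 RNA. It also drew each gene independently, so the 6 false calls do not measure false calls where many genes move together between libraries. With at least 20185098 reads in each library, a gene at 1 CPM has at least 20 reads per library, so the spread between libraries and not counting limits most comparisons.

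Alternatives set beforehand were RLE factors, no expression filter, DESeq2 1.42.0, limma's voom with quality weights, and limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean of at least 1 TPM. Further ones were the library number series as a covariate or taken separately, a surrogate variable from sva 3.50.0 as a covariate, leaving out each library, leaving out mitochondrial genes and a threshold of 0.1. Alternatives added after seeing the data were the summed pairs, the libraries with almost no Cst7 left out (also with pairs summed), the libraries over 3% ribosomal RNA left out, lemborexant 7 and vehicle 7 left out, and the hippocampal score as a covariate. The deposited effective lengths were not used beyond the check of the tables.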

Results

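Gene expression in the cerebral cortex was profiled by RNA sequencing in 19 libraries from male P301S/E4 mice, a tauopathy model named for a tau mutation that causes frontotemporal dementia and for the E4 form of apolipoprotein E. Of these, 10 came from mice given lemborexant, a dual orexin receptor antagonist prescribed for insomnia, and 9 from mice given vehicle. Lemborexant was given by gavage at 30 mg/kg each day, at zeitgeber time 13, between 7.5 and 9.5 months of age, and the vehicle was 0.5% methylcellulose. All mice were recorded as 41 weeks old. The libraries held 20185098 to 31795633 estimated reads on genes, and the totals did not differ past 0.05 between the groups (exact two-sided permutation test, p = 0.107, or 0.183 with the values of 3 nearly alike pairs averaged). The comparison asks which cortical transcripts differ after chronic blockade of the receptors for orexin, the hypothalamic peptide that sustains wakefulness. Nothing in the labels says that each library came from a separate mouse, so p-values measure the spread between these libraries.

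With all 19 libraries counted separately, cortex from lemborexant mice had lower levels of some activity-regulated and hippocampus-enriched transcripts and higher levels of several transcripts of the thalamus and striatum and of the circadian clock. None of the lists of these genes passed with an estimated correlation between genes (camera adjusted p = 0.542 to 0.579), and edgeR called 0 genes with the nearly alike libraries summed (4101 at an unadjusted p under 0.05, and 816 called without the unit of lemborexant 1 and 10) or with a hippocampal covariate (3381). Nr4a3, an immediate early transcription factor, fell from 16.6 ± 2.31 CPM (SD, n = 9) to 8.84 ± 2.73 CPM (SD, n = 10), a log2 change of -0.91 ± 0.17 (SE, edgeR adjusted p = 0.0228). Homer3, a postsynaptic scaffold protein, fell by 0.95 ± 0.17 on the log2 scale (SE, edgeR adjusted p = 0.0191). Foxp2, a transcription factor of deep cortical layers, striatum and thalamus, rose from 2.55 ± 1.26 to 11.9 ± 6.02 CPM (SD, n = 9 and 10), which was 4.67-fold (edgeR adjusted p = 0.016). With the hippocampal covariate the log2 changes of Foxp2, Nr4a3 and Homer3 were 1.34, -0.48 and -0.46, each at an edgeR adjusted p of 0.271. That covariate itself differed between the groups (below), so it also takes up part of any treatment difference. Nr1d1, the clock repressor REV-ERB alpha, rose 1.44-fold, from 132 ± 22.5 to 189 ± 36.5 CPM (SD, n = 9 and 10, edgeR adjusted p = 0.0347).

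Of 19105 genes tested, 498 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 182 higher and 316 lower after lemborexant, and 456 of them were protein-coding. The median size of their changes was 0.67 on the log2 scale, and 119 exceeded 2-fold, 75 higher and 44 lower. On log2(TPM + 1), which moved the median change of all genes from 0.03 to 0.18, limma called 130 genes, 97 higher and 33 lower, and voom with quality weights called 1149 higher and 1102 lower. These calls depended on how 3 pairs of lemborexant libraries were counted. Replicates 1 and 10, 3 and 8, and 4 and 9 differed from each other with a chi-square per degree of freedom of 3.08 to 3.66, against 12.2 to 274 for the other 168 pairs of libraries. They were tested as separate libraries, as the labels give them, and whether they are repeats of 1 RNA is not known. With the counts of each pair summed, leaving 7 lemborexant units against 9 vehicle libraries, edgeR called 0 genes, with a lowest adjusted p of 0.0711 and 4101 genes at an unadjusted p under 0.05 (961 expected by chance). Without the unit of lemborexant 1 and 10 that fit called 816 genes, 320 higher and 496 lower, and without any other unit 0 to 6. In the fit of all 16 units, 361 of the called genes passed an adjusted p of 0.1. Within the libraries numbered 1064 to 1602 (7 against 7), edgeR called 8 genes, with 4955 at an unadjusted p under 0.05, and within those numbered 859 to 933 (3 against 2) it called 0, with 910 at an unadjusted p under 0.05. In both ranges every lemborexant number (1064 to 1525 and 859 to 907) lies below every vehicle number (1574 to 1602 and 921 to 933), so an effect of the order of the numbers is confounded with treatment there. The lemborexant libraries numbered 859 to 907 (8, 9 and 10) are each nearly alike to a library of the other range. If the pairs are repeats of 1 RNA, the range from 859 to 933 holds no lemborexant RNA of its own. Leaving out 1 library moved the count from 31 (without lemborexant 9) to 1274 (without vehicle 8), and 35, 39 and 76 genes were called without lemborexant 4, vehicle 4 and vehicle 5.

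Of 36 gene lists tested, 14 passed an adjusted p of 0.05 in camera with a preset correlation, 6 higher and 8 lower after lemborexant. With an estimated correlation 0 passed, with a lowest adjusted p of 0.542, and fry's directional test passed 1, the hippocampal list (adjusted p = 0.0231). Of 100 splits of the 19 libraries into groups of 10 and 9, the real one included, 61 put at least 14 lists past the threshold, so chance cannot be excluded for the number of lists. The hippocampal, thalamic and striatal markers, the immediate early genes and the genes of oxidative phosphorylation were among the 14.

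**Figure D1:**
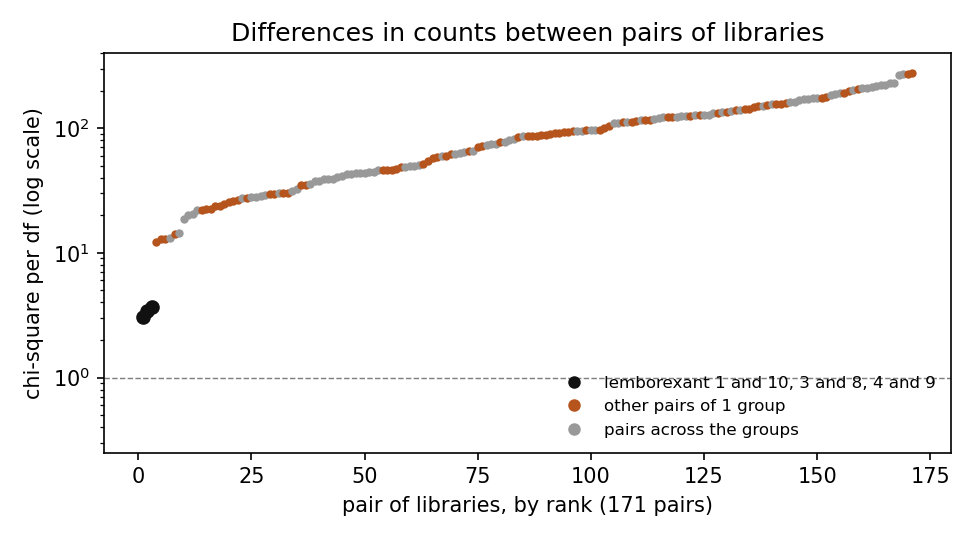
Chi-square per degree of freedom between the counts of every pair of libraries (log axis), ordered by rank over 171 pairs, with the value for pure counting noise at 1 as a dashed line. The 3 lemborexant pairs at 3.08 to 3.66 (black) lie apart from the next pair at 12.2.

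Neuropeptide transcripts of the hypothalamus were among the largest increases and stood highest in 1 library. Pmch, the precursor of melanin-concentrating hormone, stood at 1170 CPM in lemborexant replicate 7 and at 0.147 to 2.41 CPM in the other 9 lemborexant libraries, and its fitted log2 change of 7.59 ± 1.95 (SE, edgeR adjusted p = 0.0435) was 0.42 without that replicate. Avp, which encodes vasopressin, stood at 454 CPM in the same library, with a log2 change of 5.93 that became 1.74 without it. Trh (thyrotropin-releasing hormone), Gabrq (a GABA receptor subunit) and Baiap3 were likewise highest there, at 205, 56 and 189 CPM, and without it their log2 changes went from 5.98 to 3, from 4.42 to 1.42 and from 3.19 to 1.43. Gpx3, a secreted glutathione peroxidase, had a log2 change of 2.11 ± 0.48 (SE), or 1.23 without replicate 7. Without it Trh and Gpx3 stayed past the threshold (edgeR adjusted p = 0.0299 and 0.0158), while Pmch, Avp, Gabrq and Baiap3 did not. With the hippocampal score as a covariate Trh and Gpx3 had log2 changes of 0.88 and 0.98 and did not pass (edgeR adjusted p = 0.674 and 0.31). Trh was above the highest vehicle library (0.918 CPM) in all lemborexant libraries but 5 and 6, at 0.976 to 9.32 CPM outside replicate 7. Baiap3 stood at 12.5 to 14.5 CPM in lemborexant 3, 4, 8 and 9 and Avp at 4.58, 8.06 and 8.30 CPM in lemborexant 2, 4 and 9, against at most 4.61 and 2.21 CPM in vehicle libraries. Foxp2 and Vipr2 had log2 changes of at least 2.11 and 2.08 whichever library was left out, but Vipr2 did not pass in 9 of these 19 fits. Both were highest in libraries with raised thalamic scores (below). Foxp2 was 11.9 to 20.1 CPM in lemborexant 2, 3, 4, 7, 8 and 9. It was 3.37 to 9.51 CPM in lemborexant 1, 5, 6 and 10, against at most 4.73 CPM in vehicle libraries. Vipr2 was 6.49 to 10.35 CPM in lemborexant 2, 3, 7 and 8. Other lemborexant libraries held 0.697 to 2.31 CPM of it, and vehicle libraries at most 1.65 CPM. Vipr2, a receptor for the peptides VIP and PACAP, averaged 4.07 ± 3.62 against 0.802 ± 0.426 CPM (SD, n = 10 and 9), a log2 change of 2.34 ± 0.54 (SE, edgeR adjusted p = 0.0319).

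The largest decreases belonged to transcripts of hepatocytes and came mainly from vehicle replicate 7. That library held 216 CPM of Cyp2e1, a liver cytochrome P450, where the other 8 vehicle libraries held 0.0981 to 3.6 CPM. The log2 change of Cyp2e1 was -5.81 ± 1.42 (SE, edgeR adjusted p = 0.0363), and -0.89 without it. The plasma protein genes behaved alike in that library. Apoa2 went from -5.50 to -1.99 when it was left out, Apoa1 from -4.35 to -0.52, Hpx (hemopexin) from -3.48 to -0.84 and Apoh from -3.06 to -0.67. Vehicle 5 was the next highest library for Cyp2e1 and each of these genes, with Apoa2 at 17.4, Apoa1 at 6.945 and Hpx at 2.60 CPM. The remaining 3 decreases of this rank kept log2 changes of -1.30 or lower whichever library was left out. Leaving out 1 library keeps the other of a nearly alike pair, such as lemborexant 4 and 9. Klk8, the serine protease neuropsin, fell from 25.2 ± 11 to 9.15 ± 3.49 CPM (SD, n = 9 and 10), 2.76-fold (edgeR adjusted p = 0.0191). Lefty1, an antagonist of Nodal signalling, fell 2.84-fold and Sln, the calcium pump regulator sarcolipin, 3.28-fold (edgeR adjusted p = 0.0254 for both). Without lemborexant 7 and vehicle 7 edgeR called 307 genes, 111 higher and 196 lower.

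**Figure D2:**
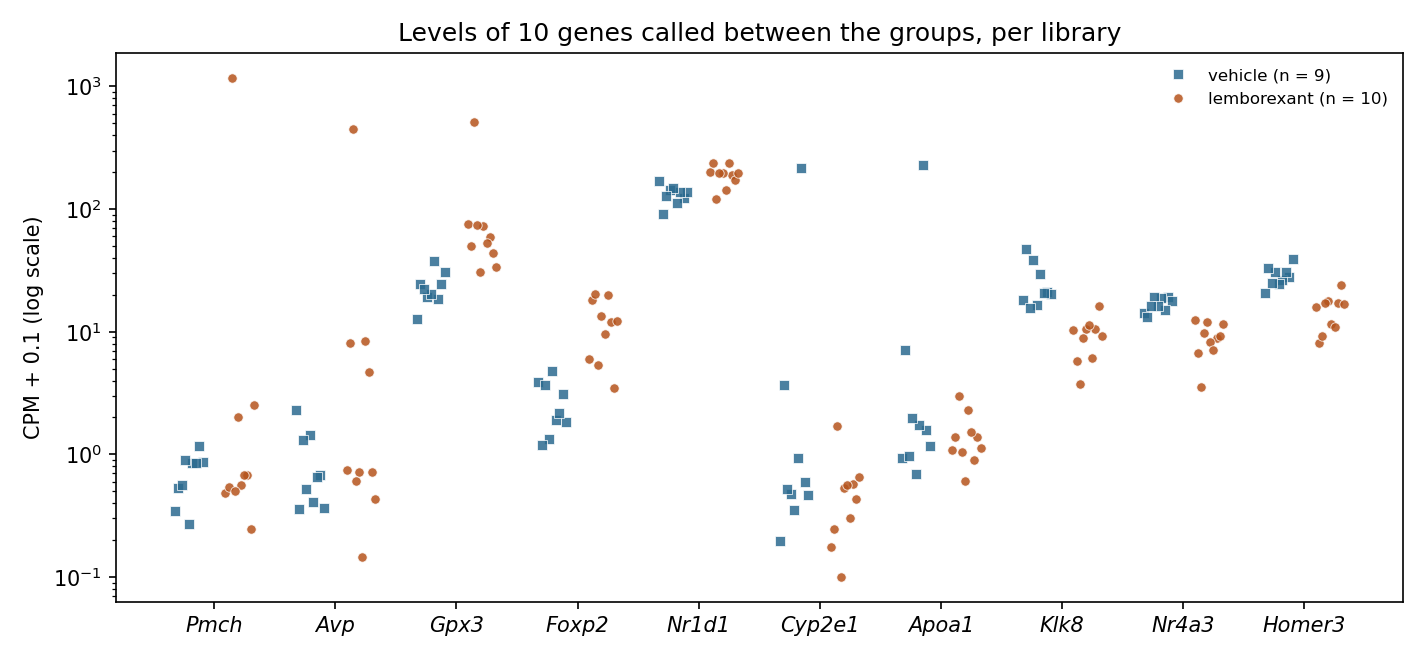
CPM plus 0.1 (log axis) of 10 genes past the threshold in each of 9 vehicle libraries (squares) and 10 lemborexant libraries (circles). Pmch and Avp are highest in lemborexant 7 at 1170 and 454 CPM, with Avp next at 8.30 CPM in lemborexant 9, Cyp2e1 and Apoa1 are highest in vehicle 7 at 216 and 230 CPM, and Foxp2, Klk8, Nr4a3 and Homer3 differ between the groups across libraries.

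In GRCm38 coordinates, Foxp2 (ENSMUSG00000029563) spans 14901349 to 15441977 on chromosome 6, and Nr4a3 (ENSMUSG00000028341) spans 48045153 to 48086447 on chromosome 4. Homer3 (ENSMUSG00000003573) spans 70282827 to 70294361 on chromosome 8, Klk8 (ENSMUSG00000064023) 43797577 to 43803826 on chromosome 7, and Nr1d1 (ENSMUSG00000020889) 98767932 to 98775333 on chromosome 11. All are annotated as protein-coding and were measured over the whole gene. Foxp2, Nr4a3, Homer3 and Klk8 were the 4 of 36 called genes chosen by the naming rule that stayed past the threshold whichever of the 19 libraries was left out, and the others lost the call without 2 to 14 of the libraries. Without vehicle 4, lemborexant 9, lemborexant 4 or vehicle 5, the call was lost for 32, 32, 31 and 28 of the 36. With the pairs summed, Foxp2, Nr4a3, Homer3 and Klk8 each had an adjusted p of 0.0711 in edgeR, and the 36 genes ranged from 0.0711 to 0.133.

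Lists of hippocampal, thalamic and striatal markers passed in camera with a preset correlation, with few members past the threshold over all genes. Of 15 hippocampal markers, 14 were lower after lemborexant, 3 fell over all genes tested and 9 adjusted over the list alone (camera adjusted p = 1.51e-07, adjusted p = 0.542 with an estimated correlation). C1ql2, a dentate gyrus gene, fell 2.06-fold and Pkp2 1.96-fold (edgeR adjusted p = 0.0441 and 0.0376). The 9 vehicle libraries had hippocampal scores, the mean centred log2 CPM of the list, of 0.27 to 0.63, while the 10 lemborexant libraries ranged from -1.20 to 0.38. The lowest were lemborexant 4, 6, 7 and 9, at -1.10, -1.20, -1.05 and -1.10. All 11 tested markers of thalamus and hypothalamus were higher, 4 rose over all genes and 10 adjusted over the list alone (camera adjusted p = 0.000247, adjusted p = 0.542 with an estimated correlation). Their scores were -0.73, -0.49, -0.59 and -0.78 in lemborexant 1, 5, 6 and 10 and -0.73 to -0.15 in the vehicle libraries, and the rise came from lemborexant 2 and 7 (1.05 and 2.63) and the nearly alike pairs 3 and 8 (1.17 and 1.12) and 4 and 9 (0.41 and 0.48). Tcf7l2, a transcription factor of thalamic neurons, rose from 34.9 ± 10.4 to 73.3 ± 39.0 CPM (SD, n = 9 and 10, edgeR adjusted p = 0.0438). Rgs16, a regulator of G protein signalling, rose 2.09-fold (edgeR adjusted p = 0.0347), and Pmch and Avp were the other members that passed. All 15 striatal markers tested were higher, 1 rose over all genes and 7 adjusted over the list alone, or 4 with the pairs summed (camera adjusted p = 0.000554, adjusted p = 0.542 with an estimated correlation). Striatal scores of lemborexant 1, 5, 6 and 10 (-0.45 to -0.08) lay inside the vehicle range (-0.60 to -0.06). That 1 was Drd1, the D1 dopamine receptor, at 7.07 ± 3.76 against 3.02 ± 1.42 CPM (SD, n = 10 and 9, edgeR adjusted p = 0.0438). The opioid precursor Pdyn and the forebrain factor Six3 had log2 changes of 1.26 ± 0.36 and 2.89 ± 0.90 (SE) and did not pass. With the hippocampal score as a covariate, chosen after seeing the data, edgeR called 0 genes, with 3381 at an unadjusted p under 0.05. Among lemborexant libraries only 1 and 10 (0.34 and 0.38) had hippocampal scores inside the vehicle range. The covariate thus overlaps with treatment, and the loss of calls does not tell tissue makeup from a treatment difference.

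**Figure D3:**
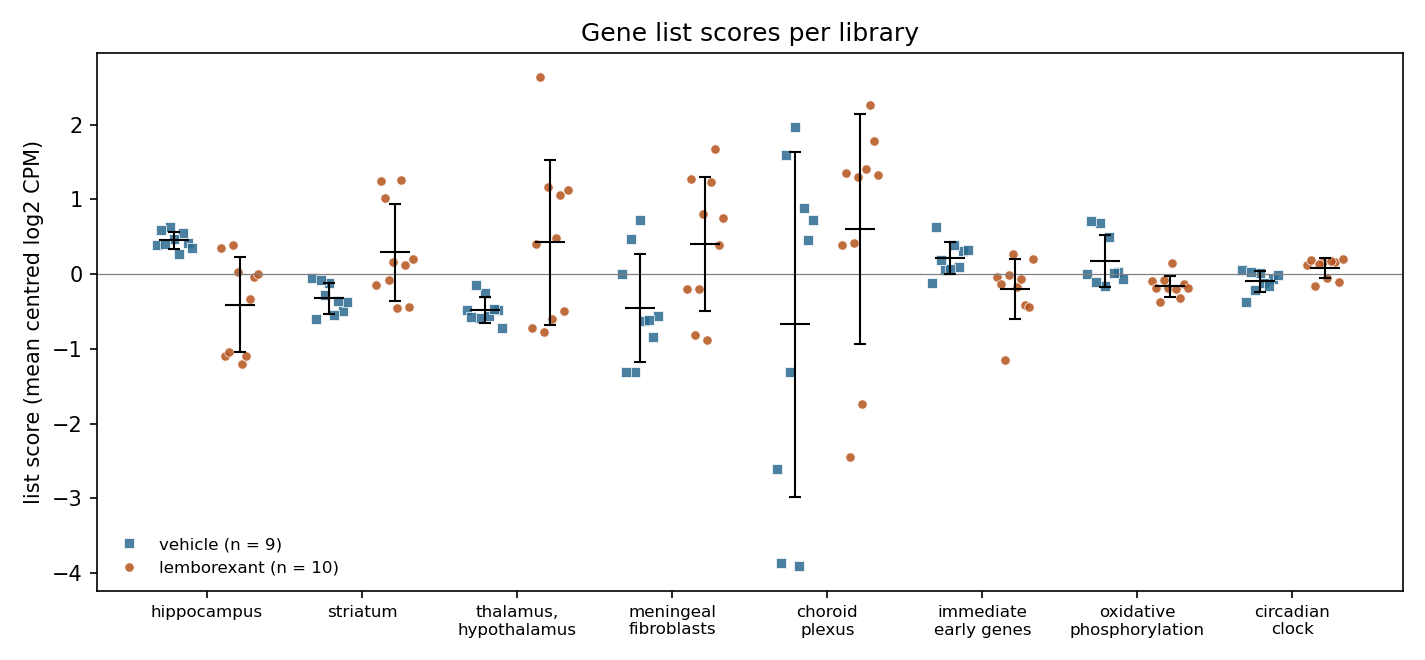
Scores of 8 gene lists (mean centred log2 CPM) in each vehicle library (squares, n = 9) and lemborexant library (circles, n = 10), with the mean and SD in black. Hippocampal scores of all vehicle libraries lie between 0.27 and 0.63, and those of lemborexant libraries reach down to -1.20.

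Lists of meningeal, endothelial and choroid plexus genes passed as higher in camera with a preset correlation, with no member past the threshold over all genes. Of 16 meningeal fibroblast genes, 15 were higher and 8 passed adjusted over the list alone, or 0 with the pairs summed (camera adjusted p = 7.71e-05, adjusted p = 0.639 with an estimated correlation). Collagen genes Col1a1 and Col1a2 had log2 changes of 1.27 ± 0.40 and 1.38 ± 0.46 (SE), and the matrix protein gene Mgp 0.91 ± 0.28. Meningeal scores were highest in lemborexant 2 (1.68) and the pairs 4 and 9 (1.27 and 1.24) and 3 and 8 (0.81 and 0.76), but -0.88 to -0.20 in lemborexant 1, 6, 7 and 10 and 0.73 and 0.47 in vehicle 8 and 9. Of 18 endothelial genes, 17 were higher and 0 passed adjusted over the list alone (camera adjusted p = 0.00598, adjusted p = 0.639 with an estimated correlation). Vwf (von Willebrand factor), the transporter gene Slco1a4 and the efflux pump gene Abcb1a had log2 changes of 0.67, 0.27 and 0.38. All 15 choroid plexus genes were higher and 0 passed adjusted over the list alone (camera adjusted p = 0.00839, adjusted p = 0.785 with an estimated correlation), and within the libraries numbered 859 to 933 the list was lower (camera adjusted p = 3.26e-15). Enpp2, Tmem72 and Calml4 had log2 changes of 0.79 ± 0.59, 0.86 ± 0.74 and 0.59 ± 0.51 (SE). Choroid plexus scores ran from -3.91 to 1.96 over vehicle libraries and from -2.45 to 2.26 over lemborexant libraries, and the camera adjusted p was 0.255 without the libraries over 3% ribosomal RNA.

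Lists of immediate early genes, postsynaptic genes and enzymes that act on tau passed as lower in camera with a preset correlation. Of 27 immediate early genes, 22 were lower after lemborexant, 2 fell over all genes and 7 adjusted over the list alone (camera adjusted p = 4.18e-05, adjusted p = 0.542 with an estimated correlation). Beside Nr4a3, Egr4 fell 2.24-fold, from 2.91 ± 1.15 to 1.30 ± 0.532 CPM (SD, n = 9 and 10, edgeR adjusted p = 0.0377). The phosphatase gene Dusp5 had a log2 change of -0.96 ± 0.26 and Arc, a synaptic plasticity gene, -0.89 ± 0.35 (SE), neither past the threshold (edgeR adjusted p = 0.0522 and 0.128). Fos stood at 40.4 ± 7.92 and 41.7 ± 16.5 CPM (SD, n = 10 and 9). Of 26 postsynaptic density genes, 22 were lower, Homer3 alone fell over all genes, and 6 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000133, adjusted p = 0.704 with an estimated correlation). Nrgn (neurogranin) had a log2 change of -0.74 ± 0.22, Dlg3 -0.41 ± 0.12 and Dlg4, which encodes PSD-95, -0.09 ± 0.10 (SE), none past the threshold. Of 25 kinases and phosphatases that act on tau, 18 were lower, 1 fell over all genes, and 9 fell and 2 rose adjusted over the list alone, or 4 and 1 with the pairs summed (camera adjusted p = 0.00643, adjusted p = 0.542 with an estimated correlation). Ppp3cb, a catalytic subunit of calcineurin, fell 1.37-fold (edgeR adjusted p = 0.0347), while Ppp3ca and the kinase gene Mark4 had log2 changes of -0.64 ± 0.18 and -0.46 ± 0.13 (SE) and did not pass. With the hippocampal score as a covariate the postsynaptic list turned to higher (camera adjusted p = 0.0403) and the tau enzyme list did not pass (camera adjusted p = 0.108). In lemborexant 7 the immediate early score was -1.15, against -0.44 to 0.27 in the other lemborexant libraries.

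Of 21 circadian clock genes, 15 were higher after lemborexant, 3 rose over all genes and 5 adjusted over the list alone (camera adjusted p = 0.0176, adjusted p = 0.579 with an estimated correlation). The 3 were nuclear receptors. Nr1d1 is given above, Rora rose 1.74-fold, from 41.7 ± 8.56 to 72.7 ± 26.7 CPM (SD, n = 9 and 10, edgeR adjusted p = 0.0314), and Rorb, which also marks layer 4 neurons, rose 1.43-fold (edgeR adjusted p = 0.0426). Rora was highest in lemborexant 2, 3 and 8, at 127, 98.1 and 93.3 CPM, where the thalamic gene Tcf7l2 was also highest (135, 122 and 123 CPM), and it was 46.6 to 54.7 CPM in lemborexant 1, 5, 6 and 10 against 25.9 to 53.7 CPM in vehicle libraries. Nr1d1 did not follow Tcf7l2 in this way, at 200 and 196 CPM in lemborexant 1 and 10, which are a nearly alike pair. It was highest in the pair 4 and 9 (235.5 and 239.2 CPM). In lemborexant 6 and 7 it was 144 and 121 CPM, inside the vehicle range of 90.3 to 168 CPM. The call of Nr1d1 was lost without 7 of the 19 libraries, and its edgeR adjusted p was 0.115 with the pairs summed. Per1, a core clock gene, stood at 18.2 ± 4.06 and 16.8 ± 4.82 CPM (SD, n = 10 and 9). With the nearly alike pairs summed the camera adjusted p was 0.0929, and within the libraries numbered 1064 to 1602 it was 0.0782. Of 24 receptors and enzymes linked to sleep, 4 rose over all genes, and 7 rose and 2 fell adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0652). Among them Ptgds, the prostaglandin D2 synthase gene, rose from 985 ± 460 to 2206 ± 999 CPM (SD, n = 9 and 10, edgeR adjusted p = 0.0417). It is also expressed in the meninges, and it was highest in lemborexant 2 (4118 CPM), where the meningeal score was highest (1.68), and lowest in vehicle 5 and 4 (514 and 533 CPM), where that score was lowest (-1.31 in each). Lemborexant 6, with 2267 CPM at a meningeal score of -0.88, departed from this. Adra1b, an alpha-1 adrenergic receptor, rose 2.28-fold (edgeR adjusted p = 0.0254).

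Lists of mitochondrial respiration, ribosomal protein and heat shock genes passed as lower in camera with a preset correlation, with no member past the threshold over all genes. Of 29 nuclear oxidative phosphorylation genes, 27 were lower, 0 fell over all genes and 24 fell adjusted over the list alone, or 14 with the pairs summed (camera adjusted p = 2.34e-10, adjusted p = 0.542 with an estimated correlation). Cox5b, Uqcrfs1 and Ndufa5 had log2 changes of -0.60 ± 0.17, -0.43 ± 0.12 and -0.63 ± 0.18 (SE). Of 13 genes of the mitochondrial genome, 12 were lower, 0 fell over all genes and 7 adjusted over the list alone, or 0 with the pairs summed (camera adjusted p = 0.000134, adjusted p = 0.542 with an estimated correlation). Cytochrome oxidase genes mt-Co1 and mt-Co3 had log2 changes of -0.54 ± 0.16 and -0.61 ± 0.19 (SE), and mt-Atp8, which overlaps its neighbour, -0.39 ± 0.12. All 34 ribosomal protein genes were lower and 0 passed adjusted over the list alone (camera adjusted p = 1.51e-07, adjusted p = 0.708 with an estimated correlation). Rps2, Rplp1 and Rpl13, which have processed pseudogenes that can share their reads, had log2 changes of -0.67, -0.60 and -0.53. Of 18 heat shock genes, 14 were lower, 0 fell over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00515, adjusted p = 0.542 with an estimated correlation). The chaperone genes Dnajb1, Hsph1 and Dnaja1 had log2 changes of -0.32 ± 0.09, -0.27 ± 0.08 and -0.25 ± 0.08 (SE). The mitochondrial genome took 5.02 ± 0.81% of reads after lemborexant and 6.48 ± 1.49% after vehicle (SD, n = 10 and 9, exact two-sided permutation test, p = 0.0147, or 0.0608 with the values of each nearly alike pair averaged). Reads fell on 27475 ± 787 genes after lemborexant and 26050 ± 962 after vehicle (SD, n = 10 and 9, exact permutation p = 0.00235, or 0.0111 with pairs averaged). A ribosomal RNA gene took 1.88 ± 0.547% and 2.54 ± 0.90% of reads (SD, n = 10 and 9, exact permutation p = 0.0682, or 0.205 with pairs averaged), and over 3% in lemborexant 6 and vehicle 3, 4 and 5. Vehicle 3, 4 and 5 also had the highest oxidative phosphorylation scores (0.49, 0.68 and 0.72, against -0.16 to 0.03 in the other 6 vehicle libraries), and their ribosomal protein scores were 0.78, 0.62 and 1.02, against -0.35 to 0.14 there and 0.77 in lemborexant 6. Without those 4 libraries both lists still passed as lower in camera with a preset correlation, and edgeR called 0 genes, with 2599 at an unadjusted p under 0.05.

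The receptors that lemborexant blocks, tau and the markers of gliosis did not differ past the threshold. Hcrtr1 and Hcrtr2, the orexin receptor genes, stood at 2.17 ± 1.57 and 4.60 ± 2.21 CPM after lemborexant (SD, n = 10) and at 1.65 ± 0.564 and 3.2 ± 0.876 CPM after vehicle (SD, n = 9), with edgeR adjusted p = 0.437 and 0.155. Both were highest in lemborexant 7 (6.34 and 10.5 CPM). Without that library their log2 changes went from 0.39 to 0.04 and from 0.53 to 0.30. Mapt, the tau gene, had a log2 change of -0.07 ± 0.21 and Prnp, the prion protein gene, -0.41 ± 0.20 (SE). The mouse genes for tau and apolipoprotein E can share reads with human forms, which were not separated here. The sources of the reads on Mapt and Apoe (0.22 ± 0.46, SE) are therefore uncertain. Snap25 (presynaptic), Mbp (myelin) and Aqp4 (astrocytic end-feet) had log2 changes of -0.09 ± 0.22, 0.15 ± 0.20 and 0.23 ± 0.36 (SE). Gfap, the astrocyte filament gene, stood at 3922 ± 2503 against 4313 ± 2565 CPM (SD, n = 10 and 9), a log2 change of -0.14 ± 0.52 (SE). Trem2, Cst7 and Clec7a, genes of plaque- and tangle-associated microglia, had log2 changes of -0.28 ± 0.55, -0.47 ± 0.90 and -0.10 ± 0.84 (SE), and P2ry12, a gene of resting microglia, -0.43 ± 0.17 (edgeR adjusted p = 0.119). Differences of the size of these SEs were not detectable in these libraries. Lemborexant 1 and 10 and vehicle 1 and 4 had almost no Cst7 (0 to 0.253 CPM, against 16.4 to 144 CPM in the other 15 libraries). Their Gfap was 430 to 582 against 3020 to 8700 CPM, and they are part of the spread behind these SEs. A possible lack of the tau transgene in them is taken up below, and the changes of the gliosis genes without them are not given here. The signs of Hcrtr1, Mapt, Apoe, Fos, Per1, Gfap, Cst7, Clec7a, Snap25, Dlg4, Mbp and Aqp4 changed in at least 1 other fit.

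In Cst7, Clec7a, Trem2 and Gfap, 4 libraries stood apart from the others labelled P301S/E4. Cst7 stood at 0.115, 0.253, 0 and 0.188 CPM in lemborexant 1, lemborexant 10, vehicle 1 and vehicle 4, and at 16.4 to 144 CPM in the other 15 libraries. Gfap stood at 430 to 582 CPM in those 4 and at 3020 to 8700 CPM in the 15, and Mapt at 311 to 468 against 574 to 1050 CPM. Clec7a stood at 0.145 to 0.47 against 20.5 to 138 CPM and Trem2 at 10 to 26.7 against 74 to 334 CPM, while P2ry12 overlapped (36.3 to 96.1 against 38.3 to 120 CPM). Without the 4, a choice made after seeing the data, edgeR called 522 genes, of which 310 were shared with the 498 in the same direction, and 0 with the remaining pairs summed (3931 at an unadjusted p under 0.05).

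**Figure D4:**
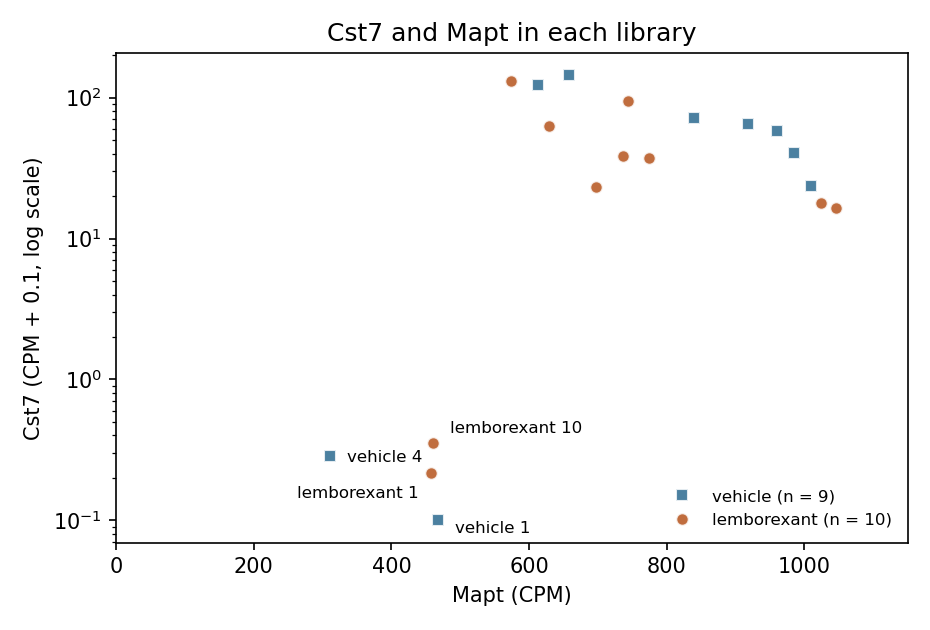
Cst7 (CPM plus 0.1, log axis) against Mapt (CPM) in each library, with vehicle as squares (n = 9) and lemborexant as circles (n = 10). Lemborexant 1, lemborexant 10, vehicle 1 and vehicle 4 lie at Cst7 of at most 0.253 CPM and Mapt of 311 to 468 CPM, and the other 15 libraries at Cst7 of 16.4 CPM or more.

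Lists of glial activation, immunity and neuron types did not pass. The 25 disease-associated microglia genes had a median log2 change of -0.06 and 0 passed adjusted over the list alone (camera adjusted p = 0.55). Lpl and Fth1 were the members with the smallest p, at log2 changes of -0.47 ± 0.26 and -0.33 ± 0.20 (SE), and Fth1 has processed pseudogenes that can share reads. Of 16 homeostatic microglia genes, 12 were lower and 0 passed adjusted over the list alone (camera adjusted p = 0.142), with Selplg at -0.44 ± 0.19 (SE). Of 24 reactive astrocyte genes, 1 rose, the elastic fibre gene Fbln5 at 1.85-fold (edgeR adjusted p = 0.0317), also adjusted over the list alone, and Cp (ceruloplasmin) had a log2 change of 0.68 ± 0.25 (SE); the list had a camera adjusted p of 0.425. Of 24 interferon genes, 19 were lower with 0 past the threshold adjusted over the list alone (camera adjusted p = 0.55), and Isg15 and Bst2 had log2 changes of -0.59 ± 0.64 and -0.37 ± 0.55 (SE). Of 22 antigen presentation and T cell genes, 1 rose, also adjusted over the list alone, and the camera adjusted p was 0.914. It was Trbc2, a T cell receptor constant gene near-identical to Trbc1 and so of uncertain count, at 6.97 ± 4.99 against 1.80 ± 1.14 CPM (SD, n = 10 and 9, edgeR adjusted p = 0.0271). Cd4 had a log2 change of 1.63 ± 0.54 (SE).

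Of 18 excitatory neuron markers, Foxp2 and Rorb rose and Neurod2, a transcription factor of excitatory neurons, fell 1.76-fold over all genes (edgeR adjusted p = 0.0403). Adjusted over the list alone 5 rose and 5 fell, and the list's median log2 change was 0.11 while camera's direction was down (camera adjusted p = 0.945). Of 18 inhibitory neuron markers, Cck, a neuropeptide gene, fell 2.01-fold (edgeR adjusted p = 0.0457), and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.384). Gad2, which makes GABA, had a log2 change of 0.36 ± 0.12 (SE). The 26 presynaptic genes had 0 past the threshold adjusted over the list alone (camera adjusted p = 0.301), with the transporter gene Slc17a6 at a log2 change of 1.42 ± 0.44 (SE). Of 25 cAMP and protein kinase A genes, the catalytic subunit gene Prkacb rose 1.56-fold (edgeR adjusted p = 0.0421) and Ppp1r1a had a log2 change of -0.61 ± 0.17 (SE). Adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.712).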

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

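Chosen only after the results were seen were the tests of the covariate, of Mapt and of the microglia genes, and all splits of the libraries except the gene counts of those that keep the nearly alike pairs whole. Some tests were also changed after their first result. The first microglia test came out in favour of few microglia, and the test on the ratio of Cst7 to P2ry12 was added only then. The ribosomal RNA test first counted as met, until r was also required to be stronger than in random sets of genes. The hippocampal and ribosomal RNA correlations were first run with 5 called genes of the thalamic and striatal lists left in by mistake, at r = -0.495 and -0.582 over 494 genes.

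Among 260 values checked within the groups (genes, list scores and library measures), 39 had 1 library far from the rest of its group. Chance gives about 13 for independent values that were not chosen by their results. That does not hold here, since the genes include those with the largest changes and many move together. Lemborexant 7 accounted for 19 and lemborexant 6 for 11. In lemborexant 7 the hypothalamic and striatal peptide genes stood highest, with Pmch at 1170, Avp at 454, Trh at 205 and Pdyn at 135 CPM, as did Gabrq at 56, Baiap3 at 189, Gpx3 at 509 and the orexin receptor gene Hcrtr2 at 10.5 CPM. Cortical and activity genes stood lowest there, with Cck at 13.6, Neurod2 at 9.77, Nrgn at 119, Nr4a3 at 3.46 and Dusp5 at 1.23 CPM, as did Ppp3cb at 55.6 and Ptgds at 608 CPM. Its list scores were -1.15 for immediate early genes, -0.374 for tau kinases and phosphatases, -1.12 for excitatory neurons and 1.47 for the olfactory bulb list, which holds Trh.

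Lemborexant 6 had the highest levels of its group for respiratory genes, with Cox5b at 294, Uqcrfs1 at 163, Ndufa5 at 197, mt-Co1 at 10600, mt-Co3 at 14200 and mt-Atp8 at 568 CPM. The same library led for Rplp1 at 704 and Rpl13 at 743 CPM, the ribosomal protein score at 0.77, ribosomal RNA at 3.23% and mitochondrial reads at 7.19%. Vehicle 4 was far from its group for Sln at 15.6, Rora at 25.9, Rorb at 49 and Ppp3cb at 163 CPM. Vehicle 7 held Cyp2e1 at 216, Apoa1 at 230, Hpx at 41.7 and Apoh at 39.8 CPM, and vehicle 3 held Vipr2 at 0.0882 CPM.

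Lemborexant 1 and 10, 3 and 8, and 4 and 9 were nearly alike, with mean differences of 0.0482 or less over 36 list scores against at least 0.0875 in other pairs. Repeat libraries from the same RNA and separate mice in a similar state are the candidate explanations. Immune receptor V segments, whose use differs between mice, correlated at 0.519, 0.339 and 0.282 within the pairs, and 0 of the 3 exceeded the highest of the other pairs (0.696). With as few as 13 V segment reads in a library of a pair, the V segments cannot tell the explanations apart. Gh, the growth hormone gene, stood at 64.01 and 63.85 CPM in lemborexant 3 and 8. It was 57.73 and 55.57 CPM in lemborexant 4 and 9, and at most 22.15 CPM in every other library. Hba-a1, a haemoglobin gene, stood at 44.71 and 42.7 CPM in lemborexant 1 and 10. Other lemborexant libraries held at most 15.8 CPM of it, and vehicle 7 held 64.21 CPM. These matches, seen after the pairs were found, argue against separate mice. The libraries of each pair carry numbers from different series (1064 and 907, 1370 and 859, 1374 and 906).

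The 498 calls between lemborexant and vehicle were tested against other splits and against tissue makeup. Within groups, over 16 units, the signed mean of 489 called genes fell with the hippocampal score (r = -0.493, permutation p = 0.0195, adjusted p = 0.026, rho = -0.574, p = 0.019), short of the -0.5 set beforehand, with r = -0.593 without the 2 farthest units and a median of -0.16 in random sets of genes. Over the 7 lemborexant units alone r was -0.722, and over the 9 vehicle libraries it was -0.569. With the ribosomal RNA share r was -0.589 (permutation p = 0.026, adjusted p = 0.026, rho = -0.535, p = 0.0441, and -0.554 without the 2 farthest). Random sets of uncalled genes, each gene signed by its own direction between the groups, gave more, with a median of -0.754. Uncalled genes thus followed the share too, so the random sets do not count against ribosomal RNA as an explanation. Over the 7 lemborexant units r was 0.0684, against -0.866 over the 9 vehicle libraries. With the hippocampal score as a covariate the median change of the called genes went from 0.67 (median SE 0.15) to 0.43 (0.19), with 0 past the threshold (edgeR, 3381 at an unadjusted p under 0.05). The score itself differed between the groups, so the covariate also takes up part of any treatment difference. A drug effect, the regional makeup of the dissected tissue and the ribosomal RNA left in the libraries therefore cannot be told apart.

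Cst7 was almost absent in lemborexant 1, lemborexant 10, vehicle 1 and vehicle 4. A candidate explanation is that these mice lacked the tau transgene, since Mapt relative to neuron genes was below all of the other 15 libraries in 4 of 4, at 1.53 to 1.91 against 2.78 to 3.55 on the log2 scale, although reads of a human transgene on Mapt were not separated here. Few microglia in the tissue is another, and the homeostatic microglia score was below the other 15 in 4 of 4 (-1.14 to -0.46 against -0.34 to 0.75). Few microglia alone is argued against by the log2 ratio of Cst7 to P2ry12, at -6.69 or lower in the 4 against -1.79 or higher in the 15. The libraries lie in both groups, and lemborexant 1 and 10 are a nearly alike pair.

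Of 100 splits of the 19 libraries, 1, the real one, called as many as 498 genes (highest other 1). Of the 100, 92 part at least 1 of the alike pairs, which the real one keeps whole, so chance is not excluded by them. With pairs kept whole, 3 of 100 called as many, the real one included, a share under 0.05, but other splits called 1357 and 2849 genes. Why they did was not tested, so the count alone does not tell treatment from other differences between the samples. With pairs summed, 5 of 100 gave at least 4101 genes at an unadjusted p under 0.05 (highest other 5255), so chance is not excluded there, and edgeR called 0 genes in the real split against 164 in another. For the number of lists, 61 of 100 put at least 14 lists past the threshold (highest other 25), as did 68 of 100 with pairs kept whole, so chance is not excluded for it.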

How the results depend on the processing

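Chosen after seeing the data were the fits with summed pairs, with libraries left out for Cst7, ribosomal RNA or hypothalamic and liver transcripts, and with the hippocampal covariate. The number of genes called, 498, stayed within 1.5 times with RLE factors (514), without mitochondrial genes (530) and without the low-Cst7 libraries (522). It was 2137 at a threshold of 0.1, 1892 in DESeq2, 2251 with voom and quality weights and 2008 with a surrogate variable. It was 254 with no expression filter, which tests more genes, 130 on log2(TPM + 1), 26 on log2(TPM + 0.1), 294 with the library series as a covariate and 307 without lemborexant 7 and vehicle 7. With fewer libraries it was 8 within numbers 1064 to 1602 and 0 within 859 to 933 (edgeR, 910 at an unadjusted p under 0.05). EdgeR called 0 with pairs summed (4101), with pairs summed and low-Cst7 libraries out (3931), without libraries over 3% ribosomal RNA (2599) and with the hippocampal covariate (3381), where the numbers in parentheses are genes at an unadjusted p under 0.05. DESeq2 and voom were run only on all 19 libraries.

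Leaving out 1 library gave 31 to 1274 genes and 14 to 17 lists. Counts moved by over 1.5 times without lemborexant 2 (237), 4 (35), 6 (1130), 8 (257) and 9 (31), and without vehicle 1 (844), 2 (250), 3 (189), 4 (39), 5 (76), 6 (275), 7 (302) and 8 (1274). With pairs summed, leaving out the unit of lemborexant 1 and 10 gave 816 genes, and leaving out any other unit gave 0 to 6. The 14 lists became 24 within numbers 859 to 933, 23 with the hippocampal covariate, 1 in fry's directional test and 0 in camera with an estimated correlation, also with pairs summed (0). The cause of these changes was not tested.

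Changes of direction were found mainly for genes that did not pass. On log2(TPM + 1) and log2(TPM + 0.1), Mapt was at 0.059 and 0.059, Fos at 0.27 and 0.28, Gfap at 0.0603 and 0.0604, Snap25 at 0.087 and 0.087 and Dlg4 at 0.17 and 0.18, and Clec7a was at 0.031 on the first and Cst7 at 0.051 on the second. Within numbers 1064 to 1602, Mapt was at 0.0399, Gfap at 0.0037 and Clec7a at 0.035. Within 859 to 933, Apoa1 was at 0.63, Hpx at 0.13, Hcrtr1 at -0.071, Apoe at -0.40, Fos at 0.36, Per1 at -0.021, Snap25 at 0.16, Mbp at -0.30, Aqp4 at -0.26, Enpp2 at -0.46, Tmem72 at -0.60 and Calml4 at -0.61. There the choroid plexus list turned to lower (camera adjusted p = 3.26e-15) and the tau enzyme list to higher (camera adjusted p = 0.877). With the hippocampal covariate Pmch was at -1.59, Avp at -2.02, Apoe at -1.31, Per1 at -0.15, Snap25 at 0.41, Dlg4 at 0.13, Mbp at -0.25, Aqp4 at -0.71, Abcb1a at -0.018 and Six3 at -0.26, and the postsynaptic list turned to higher (camera adjusted p = 0.0403). With voom Apoe was at -0.22, Fos at 0.034 and Per1 at -0.021, and with a surrogate variable Apoe was at -0.011 and Fos at 0.031. Without libraries over 3% ribosomal RNA, Fos was at 0.034, Per1 at -0.077 and Mbp at -0.074. Without lemborexant 7 and vehicle 7, Fos was at 0.0047, Clec7a at 0.0064 and Snap25 at 0.000101. With pairs summed Gfap was at 0.047 and Clec7a at 0.17, or 0.028 with the low-Cst7 libraries also left out. Leaving out 1 library gave -0.22 to 0.41 for Apoe, -0.15 to 0.095 for Fos, -0.35 to 0.047 for Gfap and -0.50 to 0.11 for Clec7a. These are log2 changes, and the cause was not tested. No paired analysis was possible because the groups share no replicate numbers in the labels.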

Other observations

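The list tests here were fixed before the data were examined, and all of the remarks on single libraries were made after their values were seen.

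Genes of other cell types and pathways were measured in the same comparison, and none of these lists passed. Of 20 oligodendrocyte and myelin genes, 19 were higher after lemborexant and 0 passed adjusted over the list alone (camera adjusted p = 0.161). Gjc3, a gap junction gene, and Myrf, the regulator of myelin genes, had log2 changes of 0.50 ± 0.16 and 0.54 ± 0.24 (SE). Precursor cell markers had a median log2 change of 0.08 (camera adjusted p = 0.652), with Neu4 at -0.29 ± 0.11 and Lhfpl3 at 0.35 ± 0.17 (SE). Pericyte and smooth muscle genes were higher in 11 of 14 (camera adjusted p = 0.0851), with Pdgfrb at 0.35 ± 0.11 and Abcc9 at 0.34 ± 0.13 (SE). Astrocyte markers had a median of 0.02 while camera's direction was down (camera adjusted p = 0.914), with Ntsr2 at -0.26 ± 0.14 and Slc4a4 at 0.20 ± 0.15 (SE). Complement genes had a median of 0.06 (camera adjusted p = 0.652), with Cfp at 0.38 ± 0.18 (SE). Blood cell genes had a median of -0.11 and a mean of 0.43 (camera adjusted p = 0.606), with the neutrophil genes S100a9 and S100a8 at 1.71 ± 0.61 and 1.83 ± 0.67 (SE).

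Of 9 olfactory bulb genes tested, Trh alone rose over all genes and 2 rose adjusted over the list alone (camera adjusted p = 0.498), and Th, the tyrosine hydroxylase gene, had a log2 change of 2.93 ± 0.87 (SE). Th stood at 53.6 CPM in lemborexant 7, against 0.470 to 1.85 CPM in the other lemborexant libraries and 0.347 to 1.25 CPM in vehicle libraries. Unfolded protein response genes were lower in 16 of 21 (camera adjusted p = 0.119), with Atf4 at -0.29 ± 0.09 and Sesn2 at -0.28 ± 0.12 (SE). Autophagy and lysosome genes had a median of -0.01 (camera adjusted p = 0.425), with Atp6v0d1 at -0.32 ± 0.09 and Map1lc3a at -0.37 ± 0.14 (SE). Lipid handling genes had a median of 0.09 (camera adjusted p = 0.652), with Scd2 at 0.30 ± 0.11 and Apod at 0.71 ± 0.32 (SE). Cholesterol synthesis genes had a median of 0.07 (camera adjusted p = 0.617), with Lss at 0.32 ± 0.15 (SE). Glucocorticoid response genes had a median of 0.02 (camera adjusted p = 0.753), with Errfi1 at -0.31 ± 0.15 and Plin4 at 0.83 ± 0.44 (SE).

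The first principal component of the libraries held 30.7% of the variance and the next held 25.4%. The disease-associated microglia score ran from -2.57 in lemborexant 10 to 1.80 in lemborexant 6.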
